A study of Drosophila melanogaster with 10 samples.

How the data were processed

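Total RNA was extracted with TRIzol, and cDNA was amplified with the Ovation Pico WTA system and labelled with biotin, per the labels' protocols. The 10 arrays fall into 5 of control RNAi (dsRNA against renilla) and 5 of nbr RNAi, collected 5 days after the dsRNA was added. The deposited levels are log2 values per probe set. GCRMA and Partek are named in the submitters' processing notes, with no versions, and the order of the steps is not given in the sources used here. GCRMA corrects the background from probe sequence and makes arrays alike by quantile normalization, so a difference in total RNA per cell would not show in these values. The array columns of the value table and of the authors' deposited statistics table were identical in 189520 of 189520 cells.

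The authors' deposited statistics table also gives a signed fold change, an unadjusted p-value, a q-value in percent and a score per probe set, per the file headers. The header writes tmr in place of nbr for the comparison, and the authors' fold equals the difference of the nbr and renilla array means to within 6.79e-05 on the log2 scale. The authors' deposited p-value equals that of an equal-variance comparison of the 2 groups to within 1% for 100% of probe sets. The tool behind the q-values and the score is not given in the sources used here. These columns were used only for a comparison with the calls made here.

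Gene names come from the symbols in the deposited table. Of 18952 probe sets, 183 were controls, and of the remaining 18769, 13773 carried 1 symbol, 665 several and 4331 none. Symbols were updated through the RefSeq table of the Release 6 plus ISO1 MT assembly, which matched 13319 probe sets by accession and 316 by symbol, and 138 kept the symbol in the file. In the gene lists, 7 symbols were not matched. No coordinates are printed, since the build behind the array files is not given in the sources used here.

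Probe sets other than controls with a mean of at least 4 on the log2 scale over the 10 arrays were tested, 7729 in all. The fit used lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, on the values as deposited, with nbr RNAi minus control RNAi as the contrast, 2-sided tests and Benjamini-Hochberg adjustment, and called an adjusted p under 0.05. Single values were compared with exact permutation tests over the 252 splits. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The fit was tested on simulated data with the means and spread of this comparison, in 5 runs with 200 changed among 7729 probe sets and genes drawn independently. It recovered 49.6% of changes of 0.3 on the log2 scale, 82.4% of 0.5, 95.2% of 1 and 98.8% of 2, and 5.78% of its calls were false. With 200 changes the adjustment is less strict than with the 2 probe sets called in the real data. These shares therefore overstate what would be found where few genes change, and in the real data Glt, at 0.97, did not pass (limma, Benjamini-Hochberg adjusted p = 0.244).

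Before the data were examined, 25 gene lists were fixed, and 18 had at least 5 measured members and were tested with camera of limma with a preset correlation of 0.01, on the brightest tested probe set of each gene. Of the remaining 7, 6 are marker lists of other cell types, and the list of transposable elements matched 1 probe set, that of the gene Max, and was not tested. The list named for cytoplasmic tRNA synthetases also matched mitochondrial ones and is called aminoacyl-tRNA synthetases here. Counts of members are given over all probe sets tested and adjusted over the list alone. Camera with an estimated correlation, and fry, were run as alternatives.

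The rule for naming genes was also fixed before the data were examined. It takes nbr, up to 12 called genes in each direction whose groups do not overlap (with fewer than 6, the smallest p values up to 6 are named as not passing), up to 4 members of each list with the smallest p, and the fixed genes AGO1, AGO2, Dcr-1, Dcr-2, loqs, r2d2, Hen1 and Eip74EF. The number named per list was set to 2 after the data were seen.

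Alternatives fixed in advance were other filters, quantile normalization, median centring, array weights, a robust fit with a trend, an unmoderated test, other thresholds, the replicate number as a block, 1 probe set per gene and leaving out each array in turn. Leaving out nbr RNAi array 5 together with control array 3, removing each array's lowess trend over the genomic span of genes, and leaving nbr out of the small RNA list, were added after the data were seen. The test of genes with miR-34 seed matches was not run, since 3' UTR sequences were not used here.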

Results

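Gene expression was measured in DL1 cells, a cultured Drosophila melanogaster line that takes up double-stranded RNA (dsRNA) from its medium. Cells were treated with dsRNA against nbr or, as the control, with dsRNA against renilla, and were collected after 5 days. Each treatment had 5 independent replicates, according to the series' design text, and each replicate was hybridised to 1 Affymetrix Drosophila_2 array, giving 10 arrays. The deposited values are log2 GCRMA levels per probe set, and the number of arrays limits the precision of each comparison. The comparison asks which genes are affected when nbr is knocked down. Nbr (Nibbler, CG9247) is an exoribonuclease that trims the 3' ends of microRNAs, and the design text names miR-34 as a microRNA that depends on it.

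The targeted gene fell in every treated culture. The nbr probe set (FlyBase FBgn0032924) had a mean log2 level of 11.35 ± 0.13 (SD, n = 5) in control RNAi and 8.19 ± 0.49 (SD, n = 5) in nbr RNAi. The log2 fold change was -3.16 with a standard error of 0.20 and a 95% interval of -3.61 to -2.71, an 8.92-fold lower level. The control arrays 1 to 5 read 11.44, 11.48, 11.38, 11.16 and 11.28, and the nbr RNAi arrays 1 to 5 read 8.48, 7.56, 8.12, 7.97 and 8.84. The difference passed limma's test with a Benjamini-Hochberg adjusted p of 1.46e-04, and a 2-sided exact permutation test gave p = 0.00794, the smallest value that the 252 splits of the arrays allow. In the RefSeq annotation of the Release 6 plus ISO1 MT assembly, nbr lies between Pld3 and Noc2. Where the dsRNA lies in the transcript relative to the probes is not given in the sources used here, and the array files name no genome build.

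Apart from nbr, 1 gene passed the test. The gene mRpS25, which encodes a protein of the small subunit of the mitochondrial ribosome, rose 2.06-fold. Its probe set (FlyBase FBgn0030572) had a mean log2 level of 10.64 ± 0.21 (SD, n = 5) in control RNAi and 11.68 ± 0.20 (SD, n = 5) in nbr RNAi. The log2 fold change was 1.04 with a standard error of 0.12, a 95% interval of 0.78 to 1.31 and a limma Benjamini-Hochberg adjusted p of 0.0163. All 5 nbr RNAi arrays, at 11.50 to 12.01, lay above all 5 control arrays, at 10.43 to 10.96, and the exact permutation p was 0.00794. The mRpS25 call was kept in limma when control array 4, nbr RNAi array 2 or nbr RNAi array 5 was left out, and was lost, with Benjamini-Hochberg adjusted p from 0.0518 to 0.0840, without control array 1, 2, 3 or 5 or nbr RNAi array 1, 3 or 4. It was also lost when probe sets with low signal were tested as well (limma, Benjamini-Hochberg adjusted p = 0.0836), with the replicate number as a block (0.423), in an unmoderated equal-variance test (0.107) and without nbr RNAi array 5 and control array 3 together (0.0578), while its log2 fold change stayed between 0.96 and 1.12 over the 10 fits that left out an array.

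**Figure D1:**
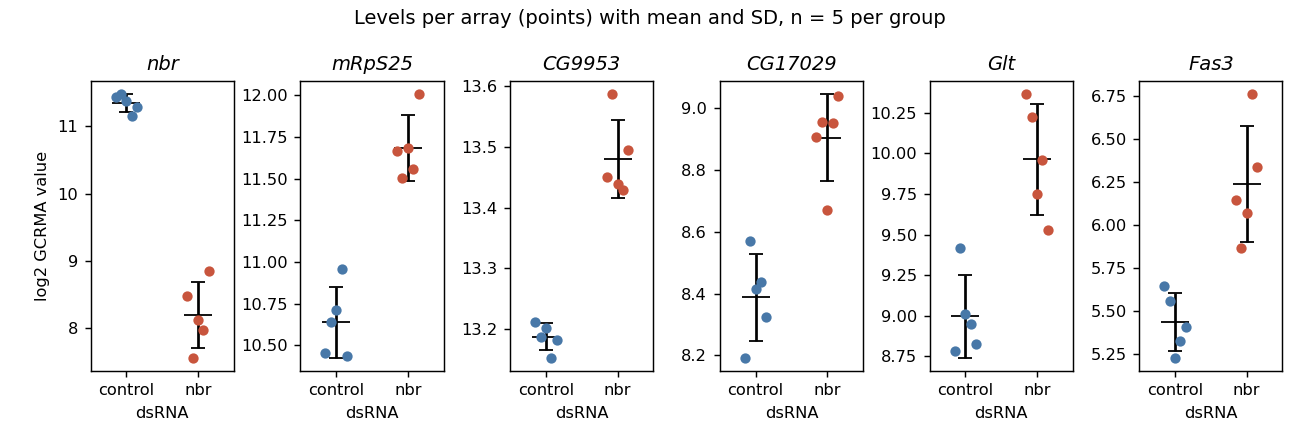
Log2 GCRMA level of nbr, mRpS25, CG9953, CG17029, Glt and Fas3 on each of the 5 control RNAi and 5 nbr RNAi arrays, with points for arrays and lines for the group mean and its SD. The nbr RNAi arrays lie below the controls for nbr, at 7.56 to 8.84 against 11.16 to 11.48, and above them for the other genes shown, of which mRpS25 passed the test.

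Of 7729 probe sets tested, limma called 2, 1 higher and 1 lower in nbr RNAi. The tested probe sets with 1 symbol stand for 6554 named genes. An unadjusted p under 0.05 was reached by 454 probe sets (5.87%), against 386 from chance alone, with 321 of them higher and 133 lower. That count rested on single arrays. It was 255 without control array 4 and 283 without control array 3, both under the 386 from chance, and 702 without control array 5 and 775 without nbr RNAi array 5. The values of the groups did not overlap for 75 probe sets (0.970%), where chance gives 0.794%. The median size of a log2 fold change was 0.056 and the median standard error 0.071. The 95% interval excluded a change of 1.5-fold or more for 7177 probe sets (92.9%) and of 2-fold or more for 7576 (98.0%).

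**Figure D2:**
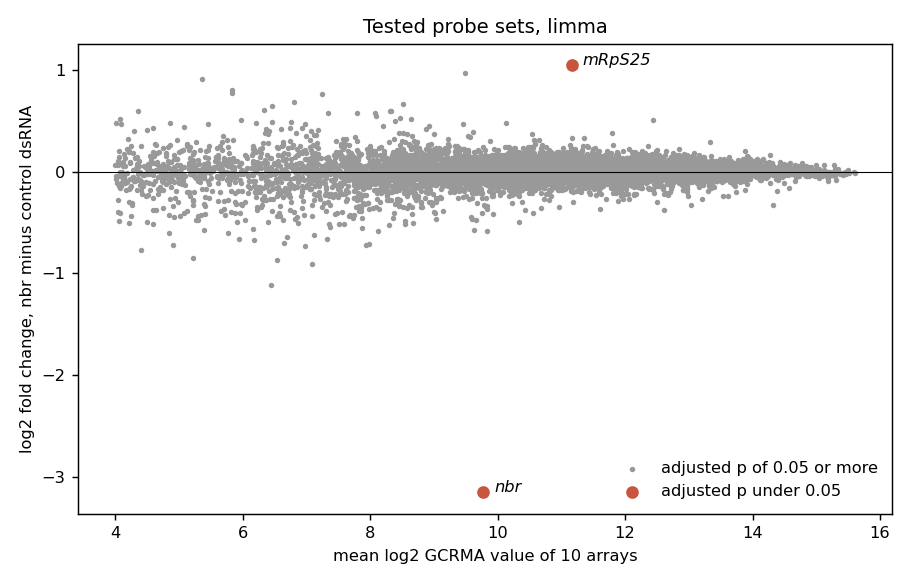
Log2 fold change (nbr RNAi minus control RNAi, vertical axis) against the mean log2 level over all 10 arrays (horizontal axis) for the 7729 probe sets tested, 1 point per probe set. The probe sets of nbr, at -3.16, and mRpS25, at 1.04, are those that passed limma's test.

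Several genes had higher levels on every nbr RNAi array than on any control array and did not pass. CG9953 had a log2 fold change of 0.29 with a standard error of 0.040 and the lowest limma Benjamini-Hochberg adjusted p after the called genes, 0.0583. Its call depended on the settings. It passed in limma with array weights (Benjamini-Hochberg adjusted p = 0.0165), a robust trend (0.0063), median centring (0.0389) and 1 probe set per gene (0.0448). It also passed in limma without the filter (0.0335) and in the unmoderated test (0.0452), where mRpS25 did not. In the fits that left out an array it did not pass (limma, Benjamini-Hochberg adjusted p from 0.0736 to 0.245). CG17029 was at 0.52, with an adjusted p of 0.147 in limma. Glt, which encodes glutactin, a basement membrane glycoprotein, was at 0.97 with a 95% interval of 0.59 to 1.35. The cell adhesion gene Fas3 (Fasciclin 3) was at 0.80 with a 95% interval of 0.46 to 1.14, at a low mean log2 level of 5.43 in control RNAi. The transcription factor gene nub was at 0.60. On the lower side, CG34126 was at -0.39, CtsK1 (a cysteine protease gene) at -0.19, CG5664 at -0.24, CG5618 at -0.19 and the kinase gene par-1 at -0.56, with limma Benjamini-Hochberg adjusted p from 0.397 to 0.849. A probe set annotated to both CG33107 and Dph5, named after its values were seen, was at -0.34 with a limma adjusted p of 0.0797. That probe set passed, with a limma Benjamini-Hochberg adjusted p of 0.0206, when nbr RNAi array 5 was left out.

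The authors' deposited table of this comparison lists 6 probe sets at a q-value of 0%, and its next lowest q-value is 8.35%. In the authors' deposited table these are nbr at -8.92-fold, mRpS25 at 2.06-fold, CG17029 at 1.43-fold, CG9953 at 1.22-fold, CtsK1 at -1.14-fold and the probe set of CG33107 and Dph5 at -1.27-fold. Both limma calls are among these 6 of the authors' deposited table. At an unadjusted p under 0.05, the authors' deposited table holds 467 of the probe sets tested here, of which 363 were also under 0.05 in limma.

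Among 21 measured genes of the small RNA pathway, nbr fell and the other 20 did not pass. AGO1, the Argonaute protein of the microRNA pathway, had a log2 fold change of 0.00070 with a 95% interval of -0.21 to 0.21. AGO2, its counterpart in the siRNA pathway, was at 0.060 (interval -0.14 to 0.26). The Dicer genes were at -0.075 for Dcr-1 and -0.047 for Dcr-2, and their partner genes were at -0.010 for loqs and 0.071 for r2d2. Hen1, the methyltransferase of small RNA 3' ends, was at 0.29 with an interval of -0.12 to 0.70, at 0.18 without nbr RNAi array 5 and at 0.47 without nbr RNAi array 2. When each array was left out in turn, AGO2 ran from 0.027 to 0.15 and Dcr-1 from -0.11 to -0.019, and neither passed. The Piwi family gene aub was at 0.39. Adjusted over the list alone, 1 gene passed as higher (aub) and 1 as lower (nbr), against 0 and 1 over all probe sets tested. The median log2 fold change of the list was 0.00070 and its mean -0.10, and limma's camera gave a Benjamini-Hochberg adjusted p of 0.960. That negative mean came from nbr itself, and over the other 20 members the mean was 0.048, with an adjusted p of 0.803 in limma's camera. AGO2 and Dcr-2 were lowest on nbr RNAi array 5, at 12.58 and 12.31.

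None of 41 measured genes of mRNA deadenylation, decapping and the exosome passed, with 1 at an unadjusted p under 0.05. The translational repressor gene pum was at 0.15 and the exosome gene Csl4 at -0.20. Adjusted over the list alone the count was also 0, and limma's camera gave a Benjamini-Hochberg adjusted p of 0.838. Eip74EF, an ecdysone-induced transcription factor gene described as a target of miR-34 in flies, was at 0.23 with a 95% interval of 0.049 to 0.41 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.849). None of the 15 measured ecdysone response genes passed, over all probe sets tested or adjusted over the list alone. Hr39, a nuclear receptor gene of the same list, was at 0.16, and 2 members had an unadjusted p under 0.05.

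Most genes of the cell cycle and of DNA replication had slightly higher mean levels in nbr RNAi, and the list was called with a preset correlation but not with an estimated one. Of 37 measured members 31 had a positive log2 fold change and 6 a negative one, with a median of 0.11. The replication licensing gene Cdc6 was at 0.23 (95% interval 0.057 to 0.40) and pav, a kinesin gene of cytokinesis, at 0.25 (0.035 to 0.47). No member passed singly in limma, over all probe sets tested or adjusted over the list alone, while 9 had an unadjusted p under 0.05, all of them higher. Limma's camera with its preset correlation of 0.01 called the list, with a Benjamini-Hochberg adjusted p of 2.49e-05. With an estimated correlation the adjusted p in camera was 0.987, and an exact permutation test of the list's mean per array (10.93 ± 0.067 against 11.05 ± 0.14, SD, n = 5) gave p = 0.119 (0.786 after Benjamini-Hochberg adjustment over the 18 lists). Without nbr RNAi array 4 the mean log2 fold change went from 0.12 to 0.075, with an adjusted p of 0.0472 in limma's camera.

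Most ribosomal protein genes, cytosolic and mitochondrial, had slightly lower mean levels in nbr RNAi, and both lists were called with the preset correlation but not with an estimated one. Of 75 measured cytosolic ribosomal protein genes 61 had a negative log2 fold change, with a median of -0.018, RpS21 at -0.090 and RpS23 at -0.067. None passed singly, adjusted over the list alone or over all probe sets tested, and 0 had an unadjusted p under 0.05 in limma. Camera in limma called the list with the preset correlation (Benjamini-Hochberg adjusted p = 0.00148), and the adjusted p was 0.987 with an estimated correlation. Of 69 measured mitochondrial ribosomal protein genes 54 had a negative log2 fold change, with a median of -0.044, and mRpS25 rose, so that 1 passed as higher and 68 did not pass. The count adjusted over the list alone was also 1, and mRpL45 was at 0.070. The Benjamini-Hochberg adjusted p of limma's camera was 0.00233 with the preset correlation, and the adjusted p was 0.987 with an estimated correlation. On nbr RNAi array 5, 68 of these 69 genes were higher than the mean of the other nbr RNAi arrays, by a median of 0.26. Exact permutation tests of the means per array gave p = 0.452 for the cytosolic list and p = 0.714 for the mitochondrial list, and both were 0.983 after adjustment over the 18 lists. The camera call of the cytosolic list was lost without control array 4 (limma, Benjamini-Hochberg adjusted p = 0.316), where its mean log2 fold change went from -0.018 to -0.0035. That mean was -0.011 without nbr RNAi array 3 and -0.030 without control array 5. The call of the mitochondrial list was lost without nbr RNAi arrays 2, 3 or 4 (0.174, 0.0553 and 0.0625) or control array 4 (0.880, with the mean turned to 0.0094). Its mean of -0.029 moved by more than 1.5 times in 8 of the 10 fits that left out an array. It was -0.012, -0.014 and -0.013 without nbr RNAi arrays 2, 3 and 4, and -0.053, -0.015 and -0.060 without control arrays 1, 3 and 5. Without nbr RNAi array 5 it was -0.081, with 17 members at an unadjusted p under 0.05 and an adjusted p of 1.98e-08 in limma's camera, while the adjusted p was 0.774 with an estimated correlation and the exact permutation p was 0.198.

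Markers of plasmatocytes, the phagocytic blood cells of the fly, did not pass as a group. Of 16 measured members 12 had a positive log2 fold change, with a median of 0.048 and a mean of 0.10. Glt was at 0.97 and SPARC, which encodes an extracellular matrix protein, at 0.19. The list had 0 members called over all probe sets tested and 1 higher, Glt, when adjusted over the list alone. Limma's camera gave a Benjamini-Hochberg adjusted p of 0.0872, and an exact permutation test of the list's mean per array gave p = 0.159 (0.786 adjusted over the 18 lists). These markers were lower on nbr RNAi array 5 than the mean of the other nbr RNAi arrays by a median of -0.22 on the log2 scale. Without nbr RNAi array 5 the mean was 0.16 and the list was called by limma's camera (Benjamini-Hochberg adjusted p = 2.25e-04), and with an estimated correlation the adjusted p was 0.541. The exact permutation p without that array was 0.00794, the smallest that the 126 splits of 9 arrays allow, and 0.0714 after Benjamini-Hochberg adjustment over the 18 lists. Without control array 5 the list was also called (limma's camera, Benjamini-Hochberg adjusted p = 0.0304). With all arrays and an estimated correlation the adjusted p in camera was 0.987. The median genomic span of these markers was 14070 bp, and across genes the fold change rose with span more without nbr RNAi array 5 (Spearman's rho 0.427, against 0.176). With the trend over span removed, the mean over all arrays was 0.080 (camera, adjusted p = 0.223). How far that trend bears on the fit without nbr RNAi array 5 was not tested.

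Marker genes of other cell types were mostly dim and none passed. The level was under the filter for 10 of 13 neuron markers, 13 of 16 muscle markers, 12 of 13 fat body markers, 7 of 11 germline markers, 4 of 8 glia markers and 6 of 10 markers of crystal cells and lamellocytes. With fewer than 5 measured members these lists were not tested as groups. Over all their members the median log2 fold changes were 0.010 for neuron, 0.011 for muscle, 0.0071 for fat body, 0.031 for germline, 0.024 for glia and 0.011 for crystal cell and lamellocyte markers. Members under the filter lie near background and give no limit on changes, so these medians near 0 say little of such genes. In a limma fit without the filter on low signal, the lowest Benjamini-Hochberg adjusted p among them was 0.829.

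None of the immune, stress and metabolic lists passed, and no member of them was called, adjusted over the list alone or over all probe sets tested. Of 14 measured genes of antimicrobial peptides and peptidoglycan recognition, the receptor gene PGRP-LC was at 0.14 and the antifungal peptide gene Drs at 0.12. Of 15 genes of JAK-STAT signalling and antiviral response, TotM was at 0.51 (95% interval 0.099 to 0.92) and the feedback inhibitor gene Socs36E at 0.12. Of 14 heat shock and chaperone genes, stv was at 0.086 and Hsp68 at 0.14. Of 16 genes of the unfolded protein response and amino acid stress, Atf6 was at 0.18 and CG10365 at 0.11. Of 18 genes of the oxidative and xenobiotic response, GstE9 was at -0.20 and Gclc at 0.058. Of 17 genes of apoptosis and JNK signalling, kay was at 0.066 and bsk at 0.047. Of 12 glycolysis genes, Ald1 was at 0.071 and Gapdh2 at 0.060. Of 20 genes of fatty acid and sterol metabolism, Desat1 was at 0.10 and Lsd-1 at 0.14. Of 14 genes of histones and chromatin, E(z) was at 0.057 and Su(z)2 at 0.15. Of 33 proteasome genes, Prosalpha3 was at -0.089 and Rpt2 at 0.076, and of 24 aminoacyl-tRNA synthetase genes LeuRS-m was at 0.11 and AlaRS at -0.11. The Benjamini-Hochberg adjusted p of limma's camera in these lists was lowest for the oxidative and xenobiotic response, at 0.497. For glycolysis, with a median of -0.0043 and a mean of 0.0054, and for the synthetases, with a median of 0.0045 and a mean of 0.0035, camera's direction was down, against the sign of the mean.

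**Figure D3:**
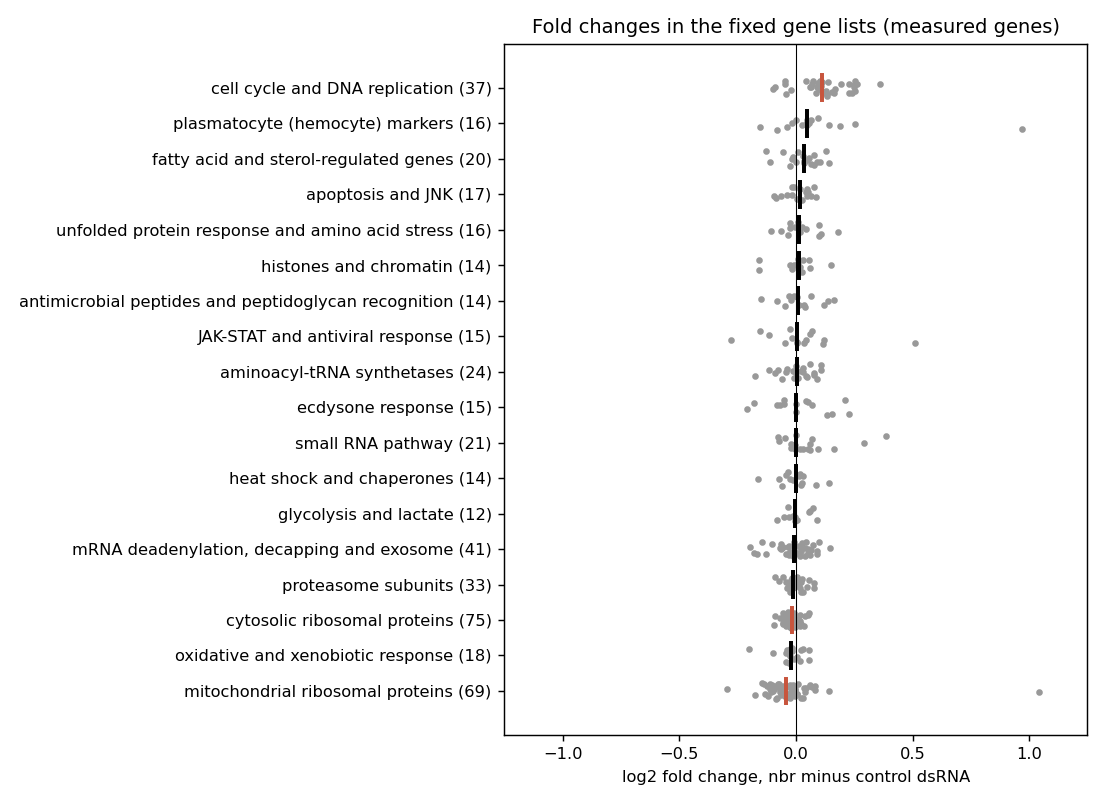
Log2 fold change (nbr RNAi minus control RNAi) of the measured members of the 18 gene lists tested, with a dot for each gene and a bar for the list's median, in red where limma's camera with its preset correlation gave a Benjamini-Hochberg adjusted p under 0.05. The 3 lists in red are the cell cycle, at a median of 0.11, and the cytosolic and mitochondrial ribosomal proteins, at -0.018 and -0.044, and 1 member, nbr, lies beyond the axis.

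Of the 10 arrays, nbr RNAi array 5 lay farthest from the others. Correlations between arrays, across probe sets, ran from 0.977 to 0.998. The root mean square distance from the median of the other arrays was 0.444 for nbr RNAi array 5 and 0.121 to 0.201 for the other 9 arrays. On that array 159 genes were lower than the mean of the other nbr RNAi arrays by 1 or more on the log2 scale and 9 were higher. On the other arrays 0 to 7 genes were lower by as much than the mean of their group's other arrays, and 33 were higher on nbr RNAi array 2 and 0 to 9 on the remaining ones. Spearman's rho across genes between genomic span and an array's difference from its group ran from -0.480 to 0.364 over the arrays other than nbr RNAi array 5, with genes not being independent. Among the lowest were Su(var)2-HP2 at -4.05, CG18537 at -4.02, Syp at -3.53 and ash1 at -3.48, named after their values were seen. Without this array limma called 3 probe sets, those of nbr, mRpS25 and the one annotated to CG33107 and Dph5.

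**Figure D4:**
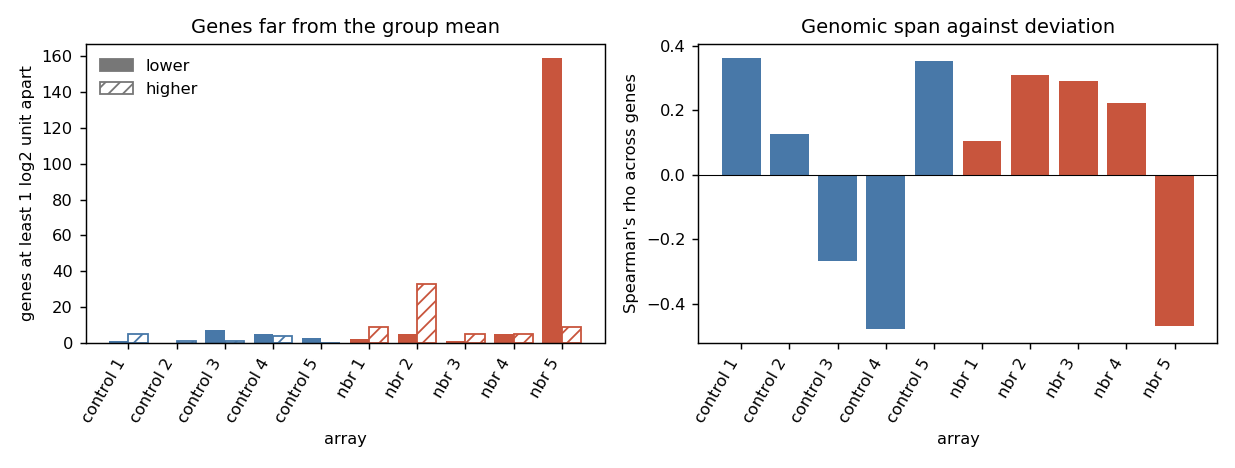
For each of the 10 arrays, the number of genes lower (filled bars) and higher (hatched bars) by 1 or more on the log2 scale than the mean of the other arrays of its group, and Spearman's rho across genes between genomic span and the array's difference from that mean. The nbr RNAi array 5 has 159 lower genes, against 0 to 7 on the other arrays, and nbr RNAi array 2 has the most higher genes, 33, while the rho of array 5, -0.469, is close to the -0.480 of control array 4.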

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

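Of the tests on nbr RNAi array 5, those of overall intensity, of weaker knockdown and of long transcripts were chosen after the result was seen. For long transcripts a rank correlation with genomic span was computed first and lay within the range of the other arrays, and it was then replaced by the removal of the trend. For weaker knockdown a distance from the control mean was computed first, and it was replaced because it nearly repeats the distance that set the array apart.

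Of 146 groups of 5 values examined, 11 held an array whose gap to its nearest neighbour was more than 0.71 of the group's range, where chance gives about 1 in 20. Of these, 7 were on nbr RNAi array 5. On that array the log2 level was 12.58 for AGO2 (nearest other 13.01), 12.31 for Dcr-2 (12.95) and 12.19 for CG10365 (11.91). The list mean there was 11.09 for histones and chromatin (11.38), 11.39 for mitochondrial ribosomal proteins (11.18) and 12.15 for the unfolded protein response and amino acid stress (12.05). The root mean square distance of nbr RNAi array 5 from the median of the other arrays was 0.444, against 0.201 for the nearest nbr RNAi array. The remaining ones were Dcr-2 at 13.02 on control array 1 (12.86), r2d2 at 12.06 on control array 5 (11.75), LeuRS-m at 10.14 on control array 4 (10.39) and kay at 14.08 on nbr RNAi array 4 (14.16).

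Technical explanations and a weaker knockdown were weighed for the distance of nbr RNAi array 5, and no other biological explanation was tested. Degraded RNA could lower 5' signal, but the mean 3' minus 5' difference over the actin and GAPDH control probe sets, which speaks only for those transcripts, was 2.00 on the log2 scale, within the 1.72 to 2.24 of the other arrays. A weaker knockdown could only bring genes back to the control level, but the 159 genes lower on nbr RNAi array 5 by 1 or more were on nbr RNAi arrays 1 to 4 above the controls by a median of only 0.156, against a median of -1.30 for array 5 minus those arrays. The 95% bootstrap interval of the 0.156, 0.138 to 0.176, resampled genes, which are not independent, so it does not give the spread over cultures. Overall intensity stays open, since quantile normalization of values already normalized that way moved no array's distance by more than 5.16%, and the 2.07 times as far from the rest that remained decides nothing. The 159 lower genes had a median genomic span of 8554 bp, against 2714 bp for other genes. The array's rank correlation of span and deviation across genes, -0.469, was not beyond the -0.480 of control array 4. With the trend over span removed it stayed 2.16 times as far. Genomic span includes introns, and the removal moved the array's distance only from 0.444 to 0.425, so a lower yield of long transcripts stays open. Across probe sets the deviations of nbr RNAi array 5 from the group mean went with those of control array 3 (r = 0.616, the highest of the 25 pairs of a control and an nbr RNAi array, with 0.465 next), which is why both were left out together in 1 alternative. A difference in this culture or its amplification, or a state shared in part with control array 3, stays open and was not tested.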

How the results depend on the processing

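Leaving out nbr RNAi array 5 with control array 3, removing the trend over genomic span, and leaving nbr out of the small RNA list, were chosen after the data were seen. The fall of nbr was called in limma under every alternative run, at -3.32 to -2.998 when each array was left out in turn (Benjamini-Hochberg adjusted p from 1.82e-05 to 0.00138). The count of 2 called probe sets (1 higher, 1 lower) was 4 with median centring and 4 with array weights (2 higher and 2 lower in each, adding CG9953 and the probe set of CG33107 and Dph5), and 3 with a robust trend and with 1 probe set per gene (2 higher in each, adding CG9953). It was 1, with 0 higher, at an adjusted p under 0.01 and without nbr RNAi array 5 and control array 3 together, where mRpS25 was at 0.98 (limma, Benjamini-Hochberg adjusted p = 0.0578). Leaving out each array in turn gave 1 to 3 called, 0 to 1 higher and 1 to 2 lower, with mRpS25 lost in 7 of 10 such fits, which have fewer samples, and 255 to 775 probe sets at an unadjusted p under 0.05, against 454 with all arrays and 901 with array weights. An unmoderated equal-variance test called 467 (331 higher, 136 lower) at an unadjusted p under 0.05, and after Benjamini-Hochberg adjustment called nbr and CG9953 but not mRpS25, as did limma without a filter, where more probe sets are tested. For the other changes the cause was not tested. Shared calls with the authors' deposited table went from 2 to 363 at an unadjusted p under 0.05.

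With the replicate number as a block, 1 probe set was called and 0 higher, and mRpS25 stayed at 1.04 (limma, Benjamini-Hochberg adjusted p = 0.423). The deviations of arrays with the same number from their group means had correlations of 0.18, 0.10, -0.47, -0.090 and -0.14 across probe sets. Of the 5 nbr RNAi arrays, 0 matched the control of its own number best. The group means include nbr RNAi array 5, which lay far from the rest, so this check showed no pairing but cannot exclude one. The block changed no other call.

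The 3 gene lists called became 0 with an estimated correlation, 0 with fry's directional test and 1, the cell cycle, with the trend over span removed, and 1 to 4 when each array was left out, with 1 left without control array 4, the cell cycle. The called mitochondrial ribosomal protein list ran from -0.081 to 0.0094 in these fits, and changed sign without control array 4. The cell cycle list kept its direction and call in all 10 of these fits, at 0.075 to 0.17.

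Of the 50 named genes that did not pass, 17 kept their sign but moved by more than 1.5 times when some array was left out, and 3 changed sign. With nbr left out, the mean of the small RNA list turned to 0.048. Results that did not pass and lay near 0 changed sign under some settings, and the cause was not tested. With quantile normalization AGO1 was at -0.0072, glycolysis at -0.0029, histones and chromatin at -0.0012 and aminoacyl-tRNA synthetases at -0.0049, and with median centring at -0.0054, -7.03e-04, -0.0053 and -0.0026. Without nbr RNAi array 5 and control array 3, Dcr-1 was at 0.011, Dcr-2 at 0.078, mRNA decay at 1.42e-04 and heat shock at 0.014. With the trend over span removed AGO1 was at -0.025, the unfolded protein response at -0.0013, apoptosis at -0.014, ecdysone response at -5.78e-04, glycolysis at -0.016, histones and chromatin at -0.021 and the synthetases at -0.018. With probe sets averaged, ecdysone response was at -0.0037 and histones and chromatin at -0.0022. When each array was left out, AGO1 ran from -0.051 to 0.082, Dcr-2 from -0.091 to 0.085, loqs from -0.031 to 0.0072, antimicrobial peptides from -0.013 to 0.039, apoptosis from -0.011 to 0.028, the synthetases from -0.020 to 0.030 and ecdysone response from -0.012 to 0.048. Glycolysis ran from -0.0095 to 0.024, heat shock from -0.031 to 0.022, histones and chromatin from -0.022 to 0.066, JAK-STAT from -0.0013 to 0.055, the proteasome from -0.021 to 0.0094 and the unfolded protein response from -0.0034 to 0.035. The test of miR-34 seed matches and its alternatives were not run. Probe sets near background, under the filter of 4, give no limit on changes of the genes they stand for.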

Other observations

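The Gene Ontology terms, the control probe sets, the test of mRpS25 without nbr RNAi array 5 the count of splits without nbr and the sorting of splits by treatment were chosen after the data were seen, and the tests of the list shifts against genomic span were set before their corrected values but after the relation of span to fold change was known.

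Of 306 Gene Ontology biological process terms in the deposited annotation, limma's camera with the preset correlation called 8, with 6 up and 2 down, and 0 with an estimated correlation, where the adjusted p was 0.955 for each of the 8. Higher were initiation of DNA replication (14 genes, median log2 fold change 0.18), DNA replication (56 genes, 0.078) and smoothened signalling (22 genes, 0.092). Lower were translation (235 genes, -0.018) and initiation of transcription by RNA polymerase II (57 genes, -0.040). A control probe set for the middle of 18S ribosomal RNA was lower in nbr RNAi, at 11.09 ± 0.10 against 11.59 ± 0.24 (SD, n = 5), with an exact permutation p of 0.00794 and a limma Benjamini-Hochberg adjusted p of 0.0328 over 40 control probe sets. The 3' and 5' probe sets of the same RNA were at -0.23 and -0.24, with limma Benjamini-Hochberg adjusted p of 0.213 and 0.713.

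The shifts of the 3 called lists were set against a trend over genomic span, since the fold change rose with span across genes (Spearman's rho 0.176, and 0.427 without nbr RNAi array 5, with genes not being independent). With the trend removed from each array the cell cycle list kept a mean log2 fold change of 0.0997 (0.12 before, limma's camera Benjamini-Hochberg adjusted p = 7.91e-05), which goes against this trend as its whole cause. With an estimated correlation the adjusted p of that list in camera was 0.881, so the call itself rests on the preset correlation. The cytosolic ribosomal protein list went from -0.018 to -0.0143 and the mitochondrial one from -0.029 to -0.0157, and their adjusted p in limma's camera became 0.255 and 0.223. Ribosomal protein genes are short, with median spans of 1356 and 909 bp, so for both lists a real shift and the trend cannot be told apart. For the cell cycle list the estimated correlation among members was 0.441, and its mean per array did not pass an exact permutation test (p = 0.119, and 0.786 adjusted over the 18 lists), so no explanation of its shift is put forward.

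For the rise of mRpS25, 3 explanations were tested. A general rise of mitochondrial ribosomal protein genes was argued against by the median of the other 68 genes, -0.044. Its 95% bootstrap interval, -0.066 to -0.027, resampled genes, which are not independent, so it does not give the spread over cultures. When each array was left out in turn, the mean of the list, mRpS25 included, ran from -0.081 to 0.0094. Signal from a neighbouring gene was argued against for CG14414, whose upper 95% limit was 0.088. For nmdyn-D6 that limit was 0.288, at a low mean log2 level of 5.25. The neighbours CG12540 and sbm lay under the filter on signal and give no limit, with sbm at 0.070 (95% interval 0.0030 to 0.137). Without nbr RNAi array 5 the log2 fold change was 0.963. If the rise is real, an effect of nbr loss on the mRpS25 transcript, or an off-target effect of the dsRNA, may lie behind it. Neither was tested. Chance also stays open, since the splits of the arrays described below cannot exclude it.

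The genes beside nbr, Coq3, Pld3, Noc2 and CG43345, had log2 fold changes from -0.091 to 0.029, and the lowest 95% limit was -0.270, which argues against a spread of the dsRNA effect to neighbours. Among 100 of the 126 splits of the arrays into groups of 5, 1 split, the real one, gave as many as 2 called probe sets, and the highest of the others gave 1. That count holds nbr, the target of the dsRNA, so it says little of other genes. With nbr left out of the fits the real split called 1, mRpS25, and the highest of the others also gave 1, CG10469, with the arrays numbered 5 exchanged. As many came from 2 of the 100 splits, the real one included. The adjustment itself makes a call rare in a split without a change, so that share largely restates the mRpS25 call and cannot exclude chance. The lowest adjusted p in limma was 0.0325 in the real split and 0.0440 in the other. The mRpS25 call was lost in 7 of 10 fits that left out an array. At an unadjusted p under 0.05, 22 splits gave as many as the real 454, so chance cannot be excluded for that count. The highest of the others, 1693, was the treatment split with the arrays numbered 5 exchanged, which keeps 8 of the 10 arrays on their treatment sides. Of the 78 splits that keep 6 of the 10 there, the fewest possible, 16 gave as many as 454. The highest of these, 1585, had control arrays 1 and 5 with nbr RNAi arrays 2, 3 and 4 on one side, which points to a structure of the samples apart from the treatment. Those arrays had the highest Spearman's rho of genomic span and deviation, 0.223 to 0.364, against -0.480 to 0.126 for the arrays on the other side. This split thus follows the trend over span, and whether the trend accounts for the count was not tested. The nbr level was 8.84 on nbr RNAi array 5 and 11.28 on control array 5.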
